A study of Mus musculus with 2 samples.

How the data were processed

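Total RNA over 200 nt was extracted from pooled stomachs with the mirVana method and 10 ng entered each library, per the labels, which also list a SMARTer Ultra Low kit manual and ERCC spike-ins. The labels give 1 group of 2 biological replicates with replicate numbers 1 and 2, and these names are used here. Reads were assigned to mm10 and annotation M4, per the deposited text files; the aligner and the quantifier are not given in the sources used here.

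The authors deposited a gene and a transcript table per library. Expected counts are the authors' estimated reads per feature, not whole because shared reads are split, per the file headers. TPM values were deposited by the authors as length-corrected shares of all transcripts, spike-ins included, and posterior mean TPM beside them. FPKM values were deposited by the authors as counts corrected for length and depth. Each gene table held 69691 rows: 43346 Ensembl genes, 96 ERCC spike-ins, 26248 features with numeric identifiers, and phiX. Of the genes, 42462 had a symbol in GENCODE M21 (GRCm38, a later release on the same assembly); for 20 symbols shared by several identifiers, the other identifiers stayed unnamed. Numeric features drew 74.99 and 27.0 expected counts and stayed out of library sizes, as did spike-ins. Symbols Muc16, Hbb-b1, Hbb-b2, Ahsp and Rn45s of the fixed lists were not matched.

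Expected counts were rounded to whole numbers, filtered with filterByExpr with a single group and scaled by TMM in edgeR 4.0.16 (R 4.3.3), which gave factors of 1.01 and 0.992. The filter asks for counts in both libraries. The log2 ratio of replicate 1 over replicate 2 used a prior count of 2. The biological coefficient of variation is the square root of edgeR's common dispersion with an intercept-only design; DESeq2 1.42.0 gave an alternative. With 1 group no quasi-likelihood test could be run, and no p-value was computed across genes except the exact binomial test of library identity with Benjamini-Hochberg adjustment. Detection meant 1 TPM or more in both libraries. The correlation used a pseudocount of 1 and list differences 0.1. A list's median ratio was set among 10000 random lists of the same size, drawn with replacement within 20 bins of mean log2 CPM. Other computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

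Checked on counts simulated from the real means for the 43346 genes, the step gave a median log2 ratio of 1.06 for genes simulated at 2-fold and 1.97 at 4-fold, put 100% of the 4-fold genes beyond 2-fold and 0.252% of unchanged genes, and gave a coefficient of variation of 10.0% where 10% was simulated. The simulated 10% lies below the 17.3% of the real pair, so the rate of 0.252% does not carry over to these libraries. On ratios shuffled over 17763 genes, 4.5% of 200 random lists of 20 genes fell outside the central 95%, and 100% did so after a shift of 0.5. Shuffling removes any joint variation of list members, so this check covers the computation only.

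Gene lists, tests, alternatives and the rule for named genes were fixed before the data were examined. Named were the 15 protein-coding nuclear genes with the highest mean TPM, the 4 highest members and the lowest of each list, any member of the sex-linked, patterning, endocrine, Hox and isoform lists, the 10 largest ratios each way among genes with a mean of 5 TPM and 100 expected counts, and the 5 largest each way among list members. In all, 8 lists were added after values had been seen: further skeletal muscle, heart muscle, cartilage, adrenal, further suprabasal squamous and further general epithelial genes, and the basal and suprabasal parts of the squamous list. Alternatives changed the threshold, unit, pseudocount, filter, scaling, tool or library used. Those leaving out skeletal muscle lists or pseudogenes, or removing a trend with length and GC content (quadratic in both, ratios bounded at 2), were added after the data were seen; GC content was known for 100% of squamous genes. Depth sets the precision: a count of 0 allows up to 3 counts.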

Results

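Total RNA of mouse stomach at embryonic day 16.5 was profiled by RNA sequencing in 2 biological replicates, each a pool of stomachs from male and female embryos of the B6NCrl strain. The labels name 41 embryos for replicate 2 and give no number for replicate 1. Both libraries belong to 1 group, so no conditions were compared; the data answer which genes the tissue expressed and how far the pools differed. The total of expected counts was 44567153 in replicate 1 and 25677702 in replicate 2. Levels are given as mean TPM (a gene's share of all transcripts, corrected for length) ± SD with n = 2 libraries unless stated otherwise. Gene positions are those of GENCODE M21 on GRCm38.

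Among nuclear protein-coding genes, blood, digestive enzyme and cytoskeletal transcripts led the profile. The haemoglobin gene Hba-a2 (ENSMUSG00000069917; chromosome 11, 32296489 to 32297298) stood at 11302 ± 246 TPM and Hbb-bs (chromosome 7, 103826534 to 103828096) at 5987 ± 192. Cym (ENSMUSG00000046213; chromosome 3, 107211293 to 107221732), which encodes the milk-clotting protease chymosin, reached 8097 ± 2780.3 TPM, and its values were 6131 and 10063 in replicates 1 and 2. Actb stood at 5221 ± 519.8, Tmsb4x at 4954 ± 372 and the fibrillar collagen gene Col3a1 (chromosome 1, 45311538 to 45349706) at 2588 ± 259 TPM. Transcripts of pancreatic enzymes were of the same order: Clps, the colipase gene, at 3259.8 ± 552, Pnliprp1 at 3182 ± 39.1 and Ctrb1, a chymotrypsinogen gene, at 2915 ± 137. In all, 15372 genes reached 1 TPM in both libraries, of which 13815 are protein-coding. Near-identical copies share reads, so the split between Hba-a1 and Hba-a2 and between Hbb-bs and Hbb-bt is uncertain.

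Squamous and simple epithelium were both detected in full. All 23 of 23 genes of the squamous forestomach list reached 1 TPM in both libraries, with a list median of 66.3 ± 23.5 TPM. Krt4 (chromosome 15, 101918535 to 101924735) and Krt13 (chromosome 11, 100117327 to 100121566), keratins of stratified mucosa, stood at 2519.6 ± 1036 and 1952 ± 632 TPM, and Ivl, the involucrin gene, was lowest at 1.36 ± 0.417. The simple epithelium list, with 21 of 21 detected, had a median of 151 ± 33.0 TPM, led by Krt8 at 1159 ± 202 and Krt19 at 1099.6 ± 244 TPM.

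Gene lists of glandular cell types differed in level, which does not measure the share of each cell type. The chief cell list had a median of 96.8 ± 16.5 TPM, with Pga5 (a pepsinogen gene) at 147 ± 49.2 and the gastric lipase gene Lipf at 0.0750 ± 0.0778. Members such as Cpb1 and Bhlha15 are not particular to chief cells, and pancreas genes were abundant (list median 317 ± 16.9 TPM). The chief median and its differences below therefore cannot be read as chief cells alone. The surface mucous list had a median of 19.1 ± 8.01, from Psca at 748 ± 439.8 and the trefoil factor gene Tff1 at 434 ± 137 to Capn9 at 0.27 ± 0.0283. The parietal list had a median of 8.75 ± 0.930; the proton pump subunit genes Atp4b and Atp4a stood at 62.8 ± 18.7 and 27.5 ± 13.7. On the log2(TPM + 0.1) scale the surface mucous median lay 1.05 ± 0.47 above the parietal one and the parietal median differed from the chief one by -3.45 ± 0.09 (SD, n = 2). The surface mucous median differed from the chief one by -2.39 ± 0.37. The squamous median was 1.81 ± 0.10 above the surface mucous median. The fundic and pyloric lists, with medians of 3.41 ± 0.244 and 3.44 ± 0.237 TPM, differed by -0.01 ± 0.004. Each difference kept its sign in both libraries and exceeded its SD. With 2 libraries the smallest two-sided p of an exact sign-flip test is 0.5, so neither these nor the later differences between lists can pass that test at 0.05.

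The endocrine list had a low median of 6.03 ± 0.0849 TPM, at percentile 28.2 of detected genes. Of its genes 15 of 23 were detected, led by Gcg, the glucagon gene, at 43.2 ± 1.65 TPM and Ghrl, the ghrelin gene, at 32.9 ± 6.65. Hdc, which makes histamine, stood at 18.6 ± 4.53, Sst (somatostatin) at 15.6 ± 4.63 and Gast (gastrin) at 9.95 ± 1.69. Neurog3, the endocrine progenitor factor, was at 3.84 ± 0.240 TPM. Gcg also stands in the pancreas list, whose genes were abundant in these libraries. The levels of endocrine genes therefore cannot be assigned to stomach endocrine cells alone.

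Of the stomach patterning factors 39 of 44 reached 1 TPM in both libraries. The mesenchymal factors Meis1 at 122 ± 3.02, Pitx1 at 88.7 ± 0.148 and Foxf1 at 81.9 ± 0.537 TPM were highest. Barx1, required for stomach specification, stood at 43.4 ± 5.54. Among epithelial factors Klf5 stood at 61.3 ± 9.28, Hnf4a at 31.1 ± 5.04, Gata4 at 22.0 ± 3.70 and Sox2 at 5.63 ± 0.339. Pdx1, from the pyloric and antral list but not particular to stomach, was at 3.52 TPM in both libraries and the intestinal factor Cdx2 at 2.42 ± 0.481. The intestinal epithelium list was detected for 17 of 18 genes, with Fabp1 at 608 ± 95.9 and Lgals4 at 303 ± 24.8. Its median exceeded that of the patterning factors, the difference being -1.34 ± 0.23 on the log2(TPM + 0.1) scale (patterning minus intestinal, SD, n = 2). Members such as Fabp1 and Lgals4 are not particular to intestine, and liver genes were also present. The list therefore cannot be read as intestinal epithelium alone.

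The wall of the organ was well represented. Smooth muscle genes were all detected (22 of 22), with Acta2 (chromosome 19, 34241090 to 34255590) at 2365 ± 349.7, Actg2 at 1654 ± 289 and Myl9 at 1428 ± 131 TPM. Interstitial cells of Cajal, the pacemaker cells, were read out by Ano1 at 53.5 ± 6.56 and Kit at 36.7 ± 4.52, and the smooth muscle median lay 2.08 ± 0.02 log2 units above theirs. Matrix genes reached a list median of 123 ± 8.12. Enteric neuron genes had a median of 9.15 ± 0.474 against 2.87 ± 0.141 for enteric glia, a log2 difference of 1.64 ± 0.14. The neural crest receptor gene Ednrb, in both lists, stood at 81.5 ± 3.30 and Uchl1 at 56.0 ± 5.48. The endothelial median was 20.8 ± 0.385 and that of macrophages 16.3 ± 0.460 TPM, led by Egfl7 at 97.5 ± 5.08 and Lyz2 at 234 ± 64.3, a log2 difference of 0.35 ± 0.01. Tcf21, in both the mesothelium and the spleen mesenchyme lists, stood at 163 ± 4.02 and the pericyte gene Kcnj8 at 50.5 ± 2.46.

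Genes of neighbouring organs were present beside these. The pancreas list had a median of 317 ± 16.9 TPM, with 20 of 21 genes detected and Amy2a5, 1 of several near-identical amylase genes, at 2121 ± 367. Liver genes had a median of 43.5 ± 3.36, with Apoa1 at 475 ± 65.6 and Afp (alpha-fetoprotein) at 369 ± 92.4. Lung and trachea epithelium was close to the floor: 1 of 10 genes was detected, Napsa at 3.61 ± 0.948, and Nkx2-1 stood at 0.01 ± 0.0141 TPM.

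**Figure D1:**
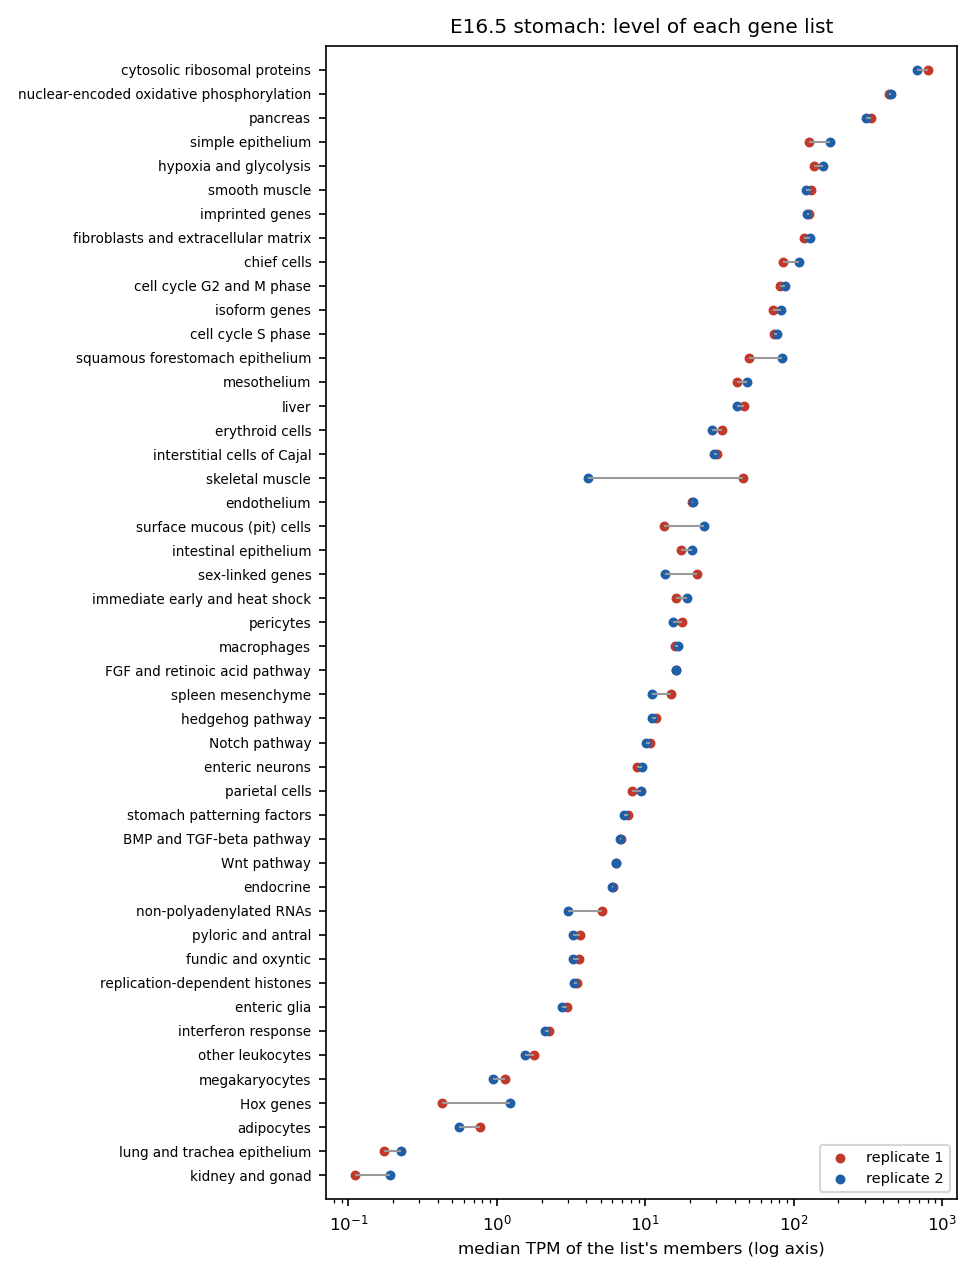
Each row is a fixed gene list of E16.5 stomach and each point the median TPM of its members in 1 library, on a log axis; a list with a median of 0 is left out. Cytosolic ribosomal proteins are at the top with 739 ± 94.0 TPM (mean ± SD, n = 2), and the skeletal muscle list has the widest gap between the libraries.

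Of the 48 fixed lists, 42 had a median of 1 TPM or more in both libraries. Signalling and proliferation lists had similar median TPM in both pools, although the Wnt pathway's median log2 ratio of -0.08 lay just outside its random range. The G2 and M phase median was 83.8 ± 4.15 TPM and the S phase median 75.4 ± 2.88, with Cdk1 at 284 ± 35.2 and Pcna at 167 ± 1.92. Pathway medians were 16.2 ± 0.0177 for FGF and retinoic acid, 11.4 ± 0.403 for hedgehog, 10.4 ± 0.396 for Notch, 6.81 ± 0.141 for BMP and TGF-beta and 6.31 ± 0.00354 for Wnt. Fgfr2 stood at 91.5 ± 14.8, Ptch1 at 19.5 ± 0.594, Hes1 at 30.0 ± 1.63, Id2 at 256 ± 6.99 and Sfrp2 at 109.7 ± 2.12 TPM.

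Hox genes of low paralog number were detected more often than those of high number. In paralog groups 1 to 5, 11 of 15 genes reached 1 TPM in both libraries, in groups 6 to 9, 7 of 12, and in groups 10 to 13, 0 of 12. Hoxc4 (16.1 ± 0.948 TPM), Hoxc5 (15.2 ± 1.52), Hoxa7 (12.0 ± 0.806) and Hoxb5 (11.4 ± 0.332) were highest. Across the 39 Hox genes the Spearman rho of level with paralog number was -0.638 in replicate 1 and -0.602 in replicate 2; genes are not independent replicates. Hoxa10 stood at 0.14 TPM in replicate 1 and 2.35 in replicate 2, so 1 gene of groups 10 to 13 passes 1 TPM when replicate 2 is taken alone.

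**Figure D2:**
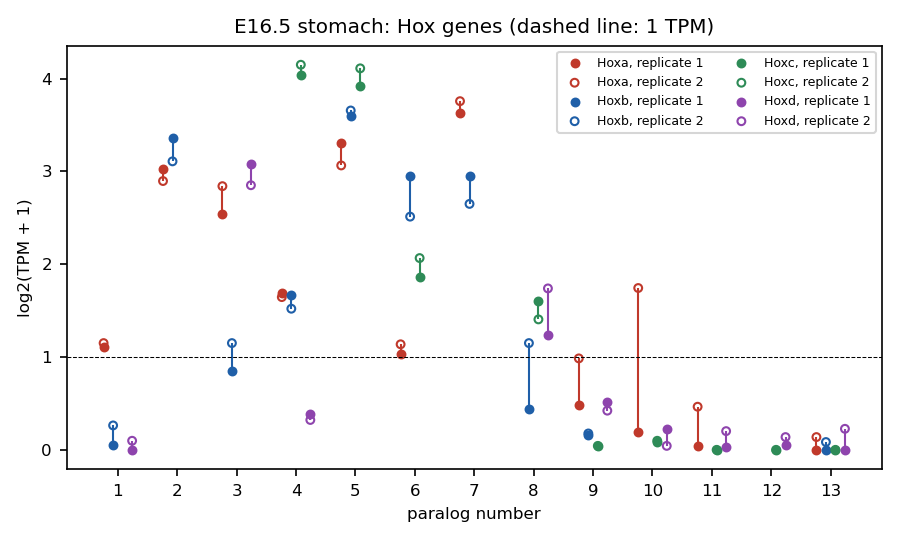
Level of each Hox gene (log2(TPM + 1)) against its paralog number, coloured by cluster, with filled points for replicate 1, open points for replicate 2 and a dashed line at 1 TPM. Paralogs 4, 5 and 7 hold the highest values and only Hoxa10 in replicate 2 exceeds the line from paralog 10 on.

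Transcript tables gave the same leading transcript in both libraries for 28 of the 30 isoform genes. For Myh11, Myl6, Barx1 and Vcl the tables hold 1 transcript, which fixes the outcome, so 24 of the 26 genes that could differ had the same one. For Trp63, a master regulator of stratified epithelium, Trp63-201 carried 38.0% ± 1.19 of the gene's TPM (SD, n = 2). Pkm-201 carried 88.3% ± 1.49 of Pkm, Tpm2-203 93.8% ± 5.05 of Tpm2 and Kit-204 49.5% ± 1.55 of Kit. The leading transcript differed for Fgfr1 and Smtn, where Fgfr1-201 and Smtn-203 led in replicate 1, with 24.6% and 41.3% of the gene, and Fgfr1-203 and Smtn-202 in replicate 2, with 20.7% and 39.9%. Transcripts of a gene share most of their sequence, so these shares are estimates.

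The pools matched closely over most genes. Across the 16621 genes at 1 TPM or more in at least 1 library, Pearson's r of log2(TPM + 1) was 0.975 and Spearman's rho 0.975; both are across genes, which are not independent replicates. Of the 17763 genes past the low-count filter, 96.4% lay within 2-fold, and the biological coefficient of variation was 17.3%. As a check that the libraries are not 1 library listed again, an exact binomial test called 5586 genes at an adjusted p under 0.05 (31.4%), and chi-square per degree of freedom was 26.8. It covers counting error only and treats amplified reads as independent, so it says nothing of how large the biological difference is.

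Skeletal muscle genes were far higher in replicate 1. All 16 of 16 skeletal muscle list members past the filter were higher there, with a median log2 ratio of 4.28 where random lists matched on expression spanned -0.11 to 0.10. Acta1, skeletal alpha-actin (ENSMUSG00000031972; chromosome 8, 123891769 to 123894751), stood at 906 and 101 TPM in replicates 1 and 2, a 9.22-fold ratio, Myl1 (chromosome 1, 66924295 to 66945404) at 405 and 17.6, Tnnc2 at 306 and 13.2 and the creatine kinase gene Ckm at 238 and 33.5. Among all genes at a mean of 5 TPM and 100 expected counts or more the highest log2 ratios belonged to Myot (5.61), Sln (5.15), Ckmt2 (5.13), Tceal7 (4.94), Ttn (4.85), Myh8 (4.85), Atp2a1 (4.85), Actn2 (4.84), Neb (4.83) and Cox6a2 (4.66). Of these, Ttn, Myh8 and Neb belong to the fixed skeletal muscle list. Atp2a1 and Cox6a2 belong to the further list, which was added after values had been seen. Absence from both lists does not make a gene one of another tissue.

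Stomach epithelial genes were lower in replicate 1 under each scaling tried. All 17 of 17 surface mucous genes and all 23 of 23 squamous genes had lower values there, with median log2 ratios of -0.56 and -0.53 against random ranges of -0.11 to 0.10 and -0.09 to 0.06. Gkn1 (chromosome 6, 87345650 to 87350942), a gastrokine of surface mucous cells, had a log2 ratio of -1.76, Gkn2 -1.64, Psca -1.24, Mucl3 -1.04 and the cornified envelope gene Sprr3 (chromosome 3, 92456502 to 92458720) -1.24. The chief cell list stood at -0.32, with 9 of 10 genes lower, and simple epithelium at -0.32, with 20 of 21. The parietal list was at -0.14, smooth muscle at -0.10, immediate early and heat shock genes at -0.13 and the Wnt pathway at -0.08, each just outside its random range.

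Liver, erythroid, leukocyte, imprinted and ribosomal protein lists were among those higher in replicate 1 relative to the median gene. Of the 15 lists above their random range 13 turned below 0 with spike-in scaling, all but skeletal muscle and kidney and gonad. The liver list had a median log2 ratio of 0.33 (18 of 18 higher), spleen mesenchyme 0.47 (7 of 7) with the spleen factor Tlx1 at 1.20, and other leukocytes 0.30 with the mast cell gene Cpa3 at 1.01. Erythroid genes stood at 0.16, macrophages at 0.12, imprinted genes at 0.20 (19 of 21) and cytosolic ribosomal proteins at 0.16 (34 of 38). The kidney and gonad list, with few genes above the floor, was at 0.94 but at 0.12 without the low-count filter, Star at 2.51 and Nr5a1 at 1.52. Enteric neurons were at 0.11; the pancreas (0.06) and nuclear-encoded oxidative phosphorylation (0.04) lists also turned below 0 with unscaled TPM. Mitochondrially encoded genes were at 0.17, replication-dependent histones at 0.18 and RNAs without a poly(A) tail at 0.49. With a trend with gene length and GC content removed, ribosomal proteins stood at 0.30, oxidative phosphorylation at 0.14, histones at 0.31, mitochondrially encoded genes at 0.11, enteric neurons at 0.07 and immediate early genes at -0.08. With unscaled TPM macrophages stood at 0.05, enteric neurons at 0.07 and the Wnt pathway at -0.13. Against the main random ranges, macrophages and enteric neurons (upper limit 0.11 for each) then no longer stood outside. With the trend removed, the same held for enteric neurons and for immediate early genes (lower limit -0.10).

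**Figure D3:**
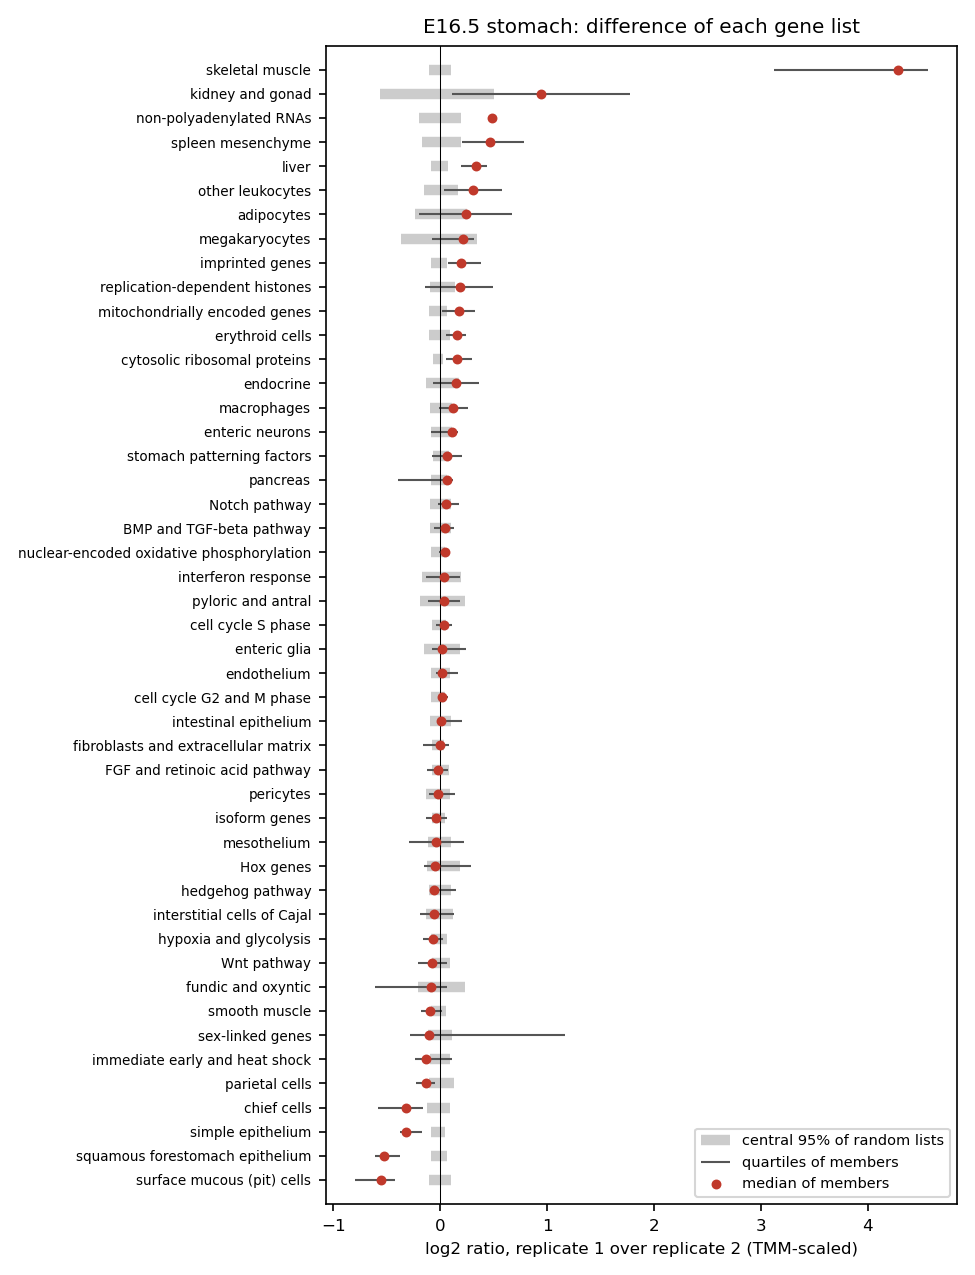
Median log2 ratio of replicate 1 over replicate 2 for each fixed list (points), quartiles of its members (thin lines) and the central 95% of medians of 10000 random lists matched on expression (grey bars). Skeletal muscle stands at 4.28, and surface mucous and squamous lists at -0.56 and -0.53.

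Of the 47 lists with a ratio, 15 lay above and 8 below the central 95% of random lists. About 2.35 would lie outside by chance if lists and genes were independent, and members of a list vary together, so the percentiles describe these libraries only. In all 220 genes were more than 2-fold higher in replicate 1 and 416 in replicate 2. Of the 653 annotated pseudogenes past the filter, 267 are among the latter and 5 among the former, and 189 protein-coding genes were higher in replicate 1 and 122 in replicate 2. Without pseudogenes 364 genes lay beyond 2-fold. Processed pseudogenes made up 8 of the 10 lowest log2 ratios, led by Gm16379 (-3.69) and Gm2423 (-3.49). Such pseudogenes share sequence with their parent genes, so their values are uncertain. Whether the pseudogene imbalance shifted the ratios of parent genes was not tested. Each side is 1 library, with no replicate check. Scaling by spike-ins shifts the median gene by -0.57 and gives 111 genes higher and 1316 lower, so all directions here are relative to the median gene; the low-count filter also leaves out genes near 0 in either library.

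Sex-linked genes differed between the pools. The Y-linked genes Eif2s3y, Ddx3y, Uty and Kdm5d stood at 31.8 and 12.8, 24.0 and 10.3, 10.6 and 4.24 and 7.10 and 3.65 TPM in replicates 1 and 2, with a mean log2 ratio of 1.20 ± 0.14 (SD over 4 genes). Xist (chromosome X, 103460366 to 103483254), the RNA that silences an X chromosome in females, stood at 20.4 and 35.2, a log2 ratio of -0.75. Eif2s3x, Ddx3x, Kdm5c and Kdm6a had log2 ratios of -0.28, -0.02, -0.29 and -0.19.

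Mitochondrially encoded genes took 1.52% of expected counts in replicate 1 (95% Wilson interval 1.51% to 1.52%) and 1.37% in replicate 2 (1.36% to 1.37%), led by mt-Atp6 at 7026 ± 32.6 TPM. Spike-ins took 3.08% (3.07% to 3.08%) and 2.05% (2.04% to 2.06%). These intervals cover counting error only. The nuclear copies Gm28437, Gm28661, Gm29216 and Gm10925, chosen after their values were seen, took a further 0.539% and 0.549% and share reads with mitochondrial genes.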

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

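No test was chosen for this part. Features with numeric identifiers, which enter no comparison, held 74.99 expected counts in replicate 1 and 27.0 in replicate 2, above the 3 counts that a count of 0 allows. The counts came from 6 and 4 features out of 26248, 3 of them shared, and 1 feature held 85 of them over both libraries. No explanation was tested.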

How the results depend on the processing

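The alternatives without skeletal muscle lists or pseudogenes and with the length and GC trend removed were chosen after the data were seen; the cause of each shift below was not tested unless given. Detected genes stayed within 1.5 times the main 15372 under each alternative run (11316 to 18443). Pearson's r of 0.975 became 0.944 with a pseudocount of 0.1, 0.991 without a filter, 0.973 at a mean of 5 TPM or more, 0.976 with FPKM and 0.980 with posterior mean TPM. The 636 genes beyond 2-fold became 1427 with spike-in scaling, 2724 without a filter, which adds low genes, and 364 without pseudogenes. The coefficient of variation of 17.3% became 19.6% without a filter, 17.7% at 100 counts or more, 13.4% as DESeq2's median, 15.6% without skeletal muscle lists and 14.7% without pseudogenes. Shares of deposited TPM were 2.82% for mitochondrial genes and 5.62% for spike-ins, against 1.44% and 2.56% of counts, since TPM divides by length. The Hox count of groups 10 to 13 ranged from 0 to 1 with 1 library left out.

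Lists outside the random range numbered 23, and 19 to 23 under the alternatives. Spike-in scaling moved skeletal muscle to 3.71, surface mucous to -1.13 and squamous to -1.11, by its shift of every gene; unscaled TPM moved skeletal muscle to 3.84. With the length and GC trend removed 13 of the 47 list medians of log2 ratios moved by over 1 SD of their random lists, surface mucous to -0.47 and squamous to -0.46. Unscaled TPM moved 14 by that much, besides 2 lists outside their random range that it took below 0. A missing filter moved 2, among them kidney and gonad to 0.12. Of the lists outside their random range, the same spike-in shift took 13 from above to below 0: enteric neurons -0.47, macrophages -0.46, other leukocytes -0.22, erythroid -0.42, pancreas -0.52, liver -0.25, spleen mesenchyme -0.11, imprinted -0.38, ribosomal proteins -0.42, oxidative phosphorylation -0.53, RNAs without a poly(A) tail -0.0900, histones -0.38 and mitochondrially encoded genes -0.40. Of the same lists, unscaled TPM did so for pancreas (-0.00476) and oxidative phosphorylation (-0.00278). Lists within their random range, such as BMP and TGF-beta, Notch and interferon response, also crossed 0 under both scalings. List levels moved by over 1 SD for 40 of 48 lists with FPKM, 25 with rescaled TPM and 11 with posterior mean TPM. FPKM and rescaled TPM change all genes of a library by close to the same factor. Their counts therefore show which lists had a small SD over the 2 libraries, not a change of lists relative to each other. Correlations, ratios and the coefficient of variation need both libraries, so none could be had with 1 left out. No paired analysis was possible because the series has 1 group.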

Other observations

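The tests of scaling, of the male share, of the squamous share and of RNA without a poly(A) tail were chosen after the result was seen, as were all 8 added lists and the genes named from them. Imprinted, glycolytic, interferon response, blood and adipocyte genes ranged widely in level. H19, an imprinted noncoding RNA, stood at 894 ± 31.3 TPM (mean ± SD, n = 2), Meg3 at 714 ± 104, Mest at 671 ± 44.0 and the fetal growth factor gene Igf2 at 597 ± 53.8. Glycolytic Ldha stood at 1622 ± 117 and Gapdh at 1367 ± 114, while Vegfa was at 3.12 ± 0.0990. Interferon response genes had a median of 2.17 ± 0.0990 TPM, with Ifitm3 at 296 ± 50.2 and Mx1 at 0.19 ± 0.0141. The neutrophil genes S100a8 and S100a9 stood at 323 ± 92.6 and 158 ± 44.7, and Cd8a at 0 in both. Of megakaryocyte genes 3 of 8 were detected, and of adipocyte genes 4 of 10, with Fabp4 at 59.4 ± 8.10.

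Genes of the adrenal list past the filter, 5 of 5, were higher in replicate 1, with a median log2 ratio of 2.51 and Akr1b7 at 13.6 and 1.28 TPM in replicates 1 and 2. Nr5a1 and Star also stand in the kidney and gonad list. Cyp11b1 (4.09 and 0.10) and Cyp21a1 (5.59 and 0.18) failed the filter because of replicate 2, and Mc2r (0.13 and 0.24) because of low counts in both. Cartilage genes, with 2 of 7 detected, had a median log2 ratio of 0.62, 5 of 5 past the filter being higher in replicate 1. No explanation was tested for these lists.

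For the skeletal muscle pattern a candidate explanation is skeletal muscle tissue in the pool of replicate 1. Further skeletal muscle genes outside the fixed list had a median log2 ratio of 2.26, with 21 of 21 higher, as that needs; 11 of 27 reached 1 TPM in both libraries, and Acta1, the most abundant gene of the fixed list, stood at 906 and 101 TPM in replicates 1 and 2. Heart muscle tissue as the source is argued against, since heart genes had a median of 0.12, 3 of 6 past the filter being higher. Myl7, the most abundant of them, stood at 26.3 and 36.1 TPM in replicates 1 and 2. Only 2 of 8 heart genes were detected, so that median rests mostly on genes near the floor. Myh6 and Mybpc3 had log2 ratios of 1.66 and 1.53 but stood at only 0.42 and 0.44 TPM in replicate 1. A small amount of heart tissue is therefore not excluded. Scaling is argued against too, the smallest median over the scalings tried being 3.71. Which muscle, and whether it came with the dissected tissue, stays open, and no biological difference between the stomachs themselves was tested for this pattern.

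For the Y-linked genes and Xist, a larger share of male embryos in replicate 1 is a candidate explanation. Other X-linked genes (516) had a median log2 ratio of 0.0349, close to the autosomal one of -0.003, and the Y-linked ratio of 2.30 with the Xist ratio of 0.596, both unlogged, solves to 54.5% male RNA in replicate 1 and 23.7% in replicate 2. That assumes equal expression per embryo. Higher Y-linked with lower Xist values always solve to possible shares, so the solution is an estimate and not a test. Because an X chromosome is silenced in females, the X-linked median would stay near the autosomal one at any male share. The Y-linked log2 ratios had an SD of 0.14 over 4 genes, and no range was computed for the shares. A single scaling factor is argued against by the log2 gap of 1.75 between the lowest Y-linked gene and Xist, whose signs were opposite under each scaling tried.

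For the squamous and surface mucous pattern, a lower share of all epithelium is argued against as the whole cause: further suprabasal genes (-0.62) and further general epithelial genes (-0.20) differed by -0.42. This contrast cannot decide on a lower share of stomach epithelium alone. General epithelial genes are not particular to stomach, and the pancreas (0.06) and intestinal epithelium (0.01) lists were not lower in replicate 1. Less advanced differentiation and a lower share of squamous epithelium cannot be told apart. The first predicts the gap of -0.42, which is -7.28 SDs of matched random lists. However, basal squamous genes (-0.48) were also below general epithelial genes, by -4.002 SDs. They are 9 of the 23 genes that defined the pattern, so their lower values were known beforehand and are no independent support. Genes of random lists are drawn independently while members of a list vary together, so these SDs can overstate a gap. The second predicts equal basal and suprabasal log2 ratios, and the gap was -0.0988 (-1.25 SDs) for the fixed suprabasal genes but -2.004 SDs, at the limit of 2 that had been set, for the further ones. Neither a squamous share nor a squamous programme covers surface mucous genes, which are glandular.

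The labels name total RNA and also a kit manual, which raises whether RNA without a poly(A) tail was captured. Rn7s1 and Rn7s2, near-identical signal recognition particle RNAs, stood at 16396 ± 3607 and 16395 ± 3605 TPM, and 46 of 67 replication-dependent histone genes reached 1 TPM in both libraries. The histone list had a low median, 3.39 ± 0.113 TPM, against 75.4 for the S phase list. The list of RNAs without a poly(A) tail had a median of 4.07 ± 1.51 TPM, with 6 of 10 genes detected. Rn7sk lay at the percentile 95.9 of detected genes in replicate 1 and 94.1 in replicate 2, just under the 95 set. The low list medians are no evidence against capture. RNA was selected by size at extraction, so any list member below that size would be lost whether or not such RNA was captured. The histone and S phase lists hold different genes, so the gap between their medians does not measure capture. Rn7s1 and Rn7s2 were high but Rn7sk fell short of the set percentile in replicate 2, so the question stays open.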
